A study of Mus musculus with 8 samples.

How the data were processed

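Total RNA from 8 mouse pancreas samples was sequenced after ribosomal depletion on an Illumina HiSeq 3000, per the labels' protocols and the series design. Per the file headers, the authors quantified transcripts with Sailfish 0.6.3, using k-mers of 20 bases, 1000 iterations and bias correction, against an index of Ensembl release 76 mouse cDNA. The submitters' processing notes also name bcl2fastq, STAR 2.0.4b, edgeR and limma, without saying what each was used for. Per the file headers, the estimated counts are reads assigned to each transcript by Sailfish and bias corrected, and they need not be whole numbers. The deposited TPM values are transcript abundances scaled within each library, also made by Sailfish and bias corrected per the file headers. The deposited transcript length was used only for length checks.

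The 8 files list the same 86127 transcripts, of which 83827 matched a gene of the GENCODE M21 annotation (GRCm38). The genome build behind the authors' index is not given in the sources used here beyond its Ensembl release, and all coordinates are those of GRCm38 in GENCODE M21. The 2300 transcripts without a match were left out of library sizes and tests. They held 3.93% to 4.23% of estimated reads in KPC and 1.45% to 3.04% in KPC-OG (exact two-sided permutation p = 0.0286, adjusted p = 0.0343 over 6 library measures). Estimated counts were summed over the transcripts of each of 29621 genes and rounded to whole numbers. A cDNA index holds no ribosomal RNA or other RNA outside it, so reads of such RNA are either lost or assigned to a transcript that shares short sequences with them. Near-identical genes share reads by estimation, and overlapping or antisense genes cannot be told apart, since strand is not stated.

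Groups and replicate numbers come from the sample titles. The main test was edgeR 4.0.16 quasi-likelihood (robust) in R 4.3.3, with TMM scaling, filterByExpr by group, no block or covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05, which left 14267 genes. Standard errors are the log2 fold change divided by the root of the F statistic. TMM factors ran from 0.483 to 0.653 in KPC and from 1.14 to 2.28 in KPC-OG, so values of low genes are less precise in KPC. A gene at 0 in a whole group is given a lower bound against a floor of 3 counts over the group, 0.148 CPM in KPC, which covers counting error only. Libraries of a group differed by far more than counting noise, with a chi-square per degree of freedom of at least 14.7 in each pair, so none was counted as a duplicate.

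The 32 gene lists were fixed before the data were examined, from textbook knowledge of acinar, ductal, endocrine, stromal, immune and neighbouring tissue. Lists with at least 3 tested members, 31 in all, were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. No list kept its camera call with an estimated correlation, where the smallest adjusted p was 0.394. Fry, which asks whether a list's genes move one way and does not compare the list with other genes, called 17 lists, which were those camera called except the interferon response list, together with the type 17 and gamma-delta T cell, mast cell, and nerve and Schwann cell lists. Shares of counts per library were compared by an exact two-sided permutation test of 70 arrangements, whose smallest p is 0.0286.

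Named genes followed a rule also fixed beforehand. It took the 12 highest and the 12 lowest log2 fold changes among protein-coding genes past the test with a mean of at least 1 CPM, no overlap between the groups, no predicted symbol and no antigen receptor segment. From each list it took up to 4 passing members with the smallest adjusted p, filled up to 2 by level, and any passing member of a list with 5 or fewer. It also took the engineered and sex genes and the 5 genes with the largest share of counts, which include Amy2a copies. Members outside the rule that are named beside a small count (Fgl1, Atf3, Muc1, Onecut1, Dmbt1, Tff2, Reg1, Reg3a, Reg3d, Fap, Chgb, Isl1, Cdkn1a, Eda2r and Zmat3) were chosen after their values were seen. Some genes that the rule names are not reported here.

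The pipeline was tested on simulated data for this comparison, with 14267 genes drawn from the real means, depths and dispersions. Of 100 genes planted with a 2-fold change edgeR recovered 66, and of 100 planted with a 4-fold change it recovered 91, with 7 unchanged genes among 167 calls. DESeq2 recovered 77 and 95 and limma-voom 54 and 89. A list planted with a 3-fold change was called by camera and no other list was. Genes were drawn independently of one another, so false calls of lists whose genes move together could not show. The genes planted singly all had an expected count above a minimum, so their recovery does not describe the lowest genes. Apart from the planted changes, both simulated groups had the same mean for each gene. The real difference in composition between the groups was thus absent, and errors of scaling could not show.

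Alternatives fixed beforehand were RLE factors, library sizes only, TMM without acinar and mitochondrial genes, DESeq2 1.42.0, limma 3.58.1 with voom, limma on log2(TPM + 1) and log2(TPM + 0.1), no filter on counts, a filter of 1 CPM in 4 libraries and 50 counts, a transcript length offset, protein-coding genes only, a threshold of 0.01, glmTreat against a 1.5-fold change, the replicate number as a block, sex as a covariate, and leaving out each library. Chosen after the data were seen were TMM without Lars2 and the genes over 8-fold lower, re-centring the library-size and TPM values of named genes on the median gene, keeping unmatched transcripts, thinning to one effective depth, the library size times the TMM factor, removing a length trend, leaving out KPC-OG 2 and KPC-OG 3, the B cell list's level as a covariate, and acinar shares with further amylase copies or without Lars2.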

Results

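Gene expression was measured by RNA sequencing of whole pancreas from C57BL/6 mice at postnatal day 42, or 6 weeks of age. KPC mice carried Cre recombinase driven by the p48 locus (Ptf1a), an oncogenic allele that Cre switches on, and a floxed Trp53 gene. KPC-OG mice carried the same alleles together with a Cre-inducible OG allele at the R26 locus, and the series presents this as an antigenic version of the model. Each genotype had 4 libraries. Estimated reads per library ranged from 7373286 to 11292570 in KPC and from 13671606 to 18292115 in KPC-OG (exact two-sided permutation p = 0.0286). Between 15072 and 16520 genes had at least 1 count in the KPC libraries, against 18680 to 20062 in KPC-OG. The labels do not state that each library came from a different mouse, so p-values measure the spread between these libraries.

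The comparison asked how the pancreas of mice with the OG allele differed from that of mice without it. The genotypes separated on the first principal component of the 500 most variable genes, which held 47.1% of the variance. The 32 acinar enzyme genes took 34.1% ± 5.10 (SD, n = 4) of gene-level counts in KPC and 25.1% ± 6.55 (SD, n = 4) in KPC-OG, a difference of -8.94 percentage points that did not pass an exact two-sided permutation test (p = 0.0857, where the smallest possible p was 0.0286). Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, was the gene with the largest share in the 4 KPC libraries, KPC-OG 3 and KPC-OG 4, while the chymotrypsinogen gene Ctrb1 was first in KPC-OG 1 and KPC-OG 2 (7.0% and 5.48%). These are reads assigned to Lars2, and the files do not show whether they came from its own messenger RNA. Lars2 held 24% ± 4.06 (SD, n = 4) of counts in KPC and 5.35% ± 1.74 (SD, n = 4) in KPC-OG (exact two-sided permutation p = 0.0286, adjusted p = 0.0343 over 6 library measures). With Lars2 left out of the total, the acinar enzyme share was 44.7% ± 5.38 in KPC and 26.6% ± 6.98 in KPC-OG, again as mean and SD of 4 libraries (exact permutation p = 0.0286), and as a share of TPM it was 49.4% ± 5.92 and 33.2% ± 7.31 (exact permutation p = 0.0286). The test was not passed with Amy2a2, Amy2a3 and Amy2a4 added to the list (difference -11.57 percentage points, exact permutation p = 0.143) or without mitochondrially encoded genes (-8.85, exact permutation p = 0.114). That last setting was meant to leave out ribosomal RNA genes too, but the index held no ribosomal RNA. Mitochondrially encoded transcripts held 0.387% ± 0.0733 of counts in KPC and 0.872% ± 0.134 in KPC-OG (n = 4 each, exact permutation p = 0.0286).

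**Figure D1:**
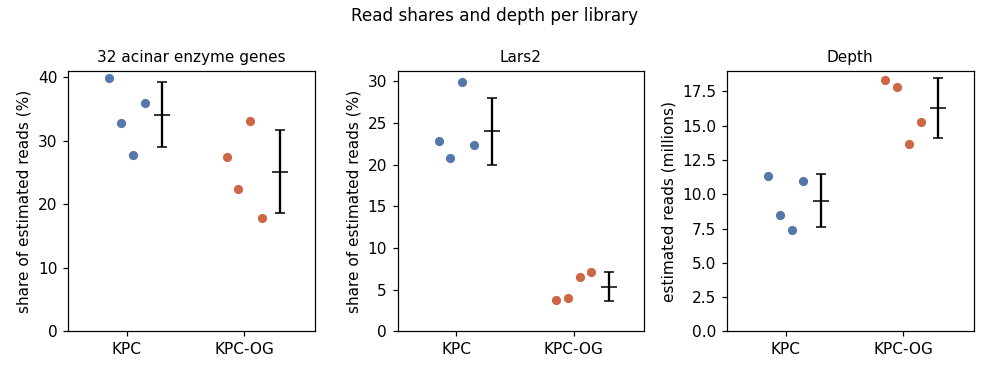
Share of gene-level estimated reads in 32 acinar enzyme genes and in Lars2, in percent, and depth in estimated reads, for each of the 8 libraries. Each point is a library, and the dash and bar to the right give the group's mean and SD (n = 4). Lars2 averages 24% in KPC and 5.35% in KPC-OG.

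Of 14267 genes tested with edgeR's quasi-likelihood test, 2486 were higher and 2373 lower in KPC-OG at an adjusted p under 0.05. At least a 2-fold change was seen in 1490 of the higher and 816 of the lower genes. These directions are relative to the typical gene, because TMM scaling was used on libraries of different composition. With library sizes alone the median log2 fold change of all tested genes lay 1.74 units above that with TMM, and 13078 genes were called higher and 99 lower in KPC-OG. Of the genes called with TMM, 1701 were then called in the opposite direction. All levels below are TMM-scaled CPM, and each log2 fold change is KPC-OG over KPC with its standard error.

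Among the genes with the largest increases, Onecut2, a homeobox transcription factor of the pancreatic duct lineage (ENSMUSG00000045991, chromosome 18, 64340020 to 64400987, GRCm38), had 0 counts in every KPC library and 22.4 ± 9.37 CPM (SD, n = 4) in KPC-OG. Against a floor of 3 counts over the KPC group this was at least 151-fold higher (edgeR adjusted p = 0.0012). Shisa6, Rgs7bp and Adcy8 were also at 0 in every KPC library, and against the same floor they were at least 19.4-fold, 16.5-fold and 15.9-fold higher. Olfm4, a marker of intestinal crypt cells, rose by 4.67 ± 0.66 (edgeR adjusted p = 0.00135) and Prap1, a secreted protein of gut epithelium, by 4.61 ± 0.51 (edgeR adjusted p = 5.37e-04). Npy, which encodes neuropeptide Y, rose by 4.98 ± 0.54 to 12.7 ± 6.49 CPM (SD, n = 4). Akr1b7, an aldo-keto reductase, rose by 4.79 ± 0.71. Bmx, a Tec family tyrosine kinase, Dlgap1, a postsynaptic scaffold protein, and Asz1, a germ cell protein, were near 0 in KPC and rose to 4.32 ± 2.28, 1.99 ± 0.501 and 2.61 ± 0.594 CPM (SD, n = 4; edgeR adjusted p = 0.00125, 0.00118 and 8.25e-04). Fabp1, the liver and gut fatty acid binding protein, was higher in KPC-OG (edgeR adjusted p = 0.0362), with 8.71 and 8.64 CPM in KPC-OG 2 and KPC-OG 3 and 0.548 and 0.595 CPM in KPC-OG 1 and KPC-OG 4. The Fabp1 call was lost without any KPC library, KPC-OG 2 or KPC-OG 3 (adjusted p up to 0.13), and without both KPC-OG 2 and KPC-OG 3 (adjusted p = 0.151). Limma-voom gave adjusted p = 0.0702 for Npy, 0.0866 for Akr1b7, 0.0854 for Olfm4 and 0.448 for Fabp1.

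Among the genes with the largest decreases, Gdf7, a BMP family growth factor (ENSMUSG00000037660, chromosome 12, 8297918 to 8301954, GRCm38), fell by 8.44 ± 0.86 on the log2 scale, from 95.9 ± 37.2 to 0.394 ± 0.613 CPM (SD, n = 4; edgeR adjusted p = 6.87e-04). The homeobox genes Dlx6, En1, Six3 and Hoxd11 fell by 6.02, 4.97, 4.27 and 4.14, and the forkhead gene Foxe3 fell by 4.12. Lalba, which encodes the milk protein alpha-lactalbumin, fell by 4.69, and Oprm1, the mu opioid receptor gene, fell by 4.05. Wdr17 fell by 5.31, Bcorl1 by 4.96, Slfn14 by 4.86, and Whrn also fell (-4.37). Reads assigned to Lars2 (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666, GRCm38) fell by 3.78 ± 0.67 (edgeR adjusted p = 0.00249). Within groups, the levels of the 45 other genes over 8-fold lower followed those of Lars2 (median r = 0.92, exact one-sided permutation p = 0.00347). Within KPC-OG, Lars2 was highest in KPC-OG 3 as TMM-scaled CPM (57660) and in KPC-OG 4 as a share of counts (7.12%, against 6.57% in KPC-OG 3). In KPC-OG 3 Gdf7, Dlx6, Wdr17 and Whrn were also higher than in the other 3 libraries of the group.

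The acinar program fell relative to the typical gene. In the acinar enzyme list 22 of 31 tested members fell, 1 rose and 8 did not pass, with 27 lower and 2 higher when adjusted over the list alone. The list's median log2 fold change was -2.01 (camera adjusted p = 5.84e-10, but adjusted p = 0.458 with an estimated correlation). Cpb1, carboxypeptidase B1 (ENSMUSG00000011463, chromosome 3, 20248264 to 20275733, GRCm38), fell by 2.55 ± 0.58, from 55432 ± 15306 to 9450 ± 7064 CPM (SD, n = 4; edgeR adjusted p = 0.00785). Rnase1, pancreatic ribonuclease, fell by 2.41 ± 0.47 and Amy1, an amylase, by 1.88 ± 0.42. Prss3, a trypsinogen, was the member that rose, by 3.16 ± 0.60. Ctrb1, chymotrypsinogen B1, fell by 1.68 ± 0.46 (edgeR adjusted p = 0.0182), a call lost without KPC 1 (adjusted p = 0.0566) or without KPC-OG 2 (adjusted p = 0.0538). As a share of counts, Ctrb1 held 4.75% ± 0.912 in KPC and 5.0% ± 1.78 in KPC-OG (SD, n = 4). The pancreatic amylase copies Amy2a2, Amy2a3 and Amy2a5 are near-identical and shared their reads. Their log2 fold changes were all -1.76 with edgeR adjusted p = 0.052, and -2.62 (adjusted p = 2.63e-04) without KPC-OG 3. They also passed with DESeq2 (adjusted p = 0.0284), limma-voom (0.0175), a transcript length offset (up to 0.0492), sex as a covariate (up to 0.0294) and the replicate number as a block (up to 0.0286). After re-centring on the median gene they passed with library sizes only (5.66e-04) and TPM (up to 7.65e-04). As a share of counts, Amy2a2 to Amy2a5 together held 17.1% ± 3.25 in KPC and 13.6% ± 7.41 in KPC-OG (SD, n = 4). In the acinar identity list 15 of 16 tested members fell and 1 rose, the same counts when adjusted over the list alone, with a median of -1.71 (camera adjusted p = 5.84e-10, adjusted p = 0.403 with an estimated correlation). Rbpjl, a partner of the acinar transcription factor Ptf1a, fell by 1.59 ± 0.27. Gata4, a transcription factor, fell by 1.15 ± 0.13, Gatm, which makes the creatine precursor, by 2.11 ± 0.29, and Rab3d, a zymogen granule GTPase, by 1.47 ± 0.21. The member that rose was Fgl1, a secreted hepatokine (1.01). In the list of ER stress and secretory load genes 10 of 19 fell, 1 rose and 8 did not pass (12 lower and 1 higher adjusted over the list alone), with a median of -0.71 (camera adjusted p = 1.41e-04, adjusted p = 0.458 with an estimated correlation). Edem1 and Dnajc3, which act in protein quality control in the endoplasmic reticulum, fell by 1.93 ± 0.29 and 1.68 ± 0.25, and the stress transcription factor Atf4 fell by 0.94 ± 0.18, while Atf3, another stress transcription factor, rose by 1.32. These decreases are relative to the typical gene, and relative to the median gene with library sizes only the medians of the acinar enzyme, acinar identity and ER stress and secretory load lists were -2.17, -1.89 and -0.70.

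Duct and gastric-type epithelial genes rose. In the duct cell list 14 of 21 tested members rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 1.03, which is the same with Onecut2 at its lower bound (camera adjusted p = 4.31e-07, adjusted p = 0.458 with an estimated correlation). The keratin gene Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665, GRCm38) rose by 2.46 ± 0.28, from 31.0 ± 9.03 to 171 ± 51.8 CPM (SD, n = 4; edgeR adjusted p = 5.58e-04). Krt7 rose by 2.12 ± 0.20, the tight junction gene Cldn4 by 2.28 ± 0.24 and the chloride channel gene Cftr by 2.22 ± 0.25. Those that fell were the mucin gene Muc1 (-0.81) and the transcription factor gene Onecut1 (-0.90). In the list of gastric-type metaplasia and PanIN genes, PanIN being the precursor lesion of pancreatic cancer, 17 of 21 rose, 2 fell and 2 did not pass (18 and 2 adjusted over the list alone), with a median of 2.31 (camera adjusted p = 5.84e-10, adjusted p = 0.394 with an estimated correlation). Ctse, which encodes cathepsin E, rose by 3.58 ± 0.37 from 18.7 ± 6.41 to 224 ± 89.5 CPM (SD, n = 4; edgeR adjusted p = 5.05e-04). The gastrokine gene Gkn3 rose by 3.28 ± 0.38, and the annexin gene Anxa10 by 2.67 ± 0.27. Dmbt1 and the trefoil factor gene Tff2 fell, by 1.97 and 0.83. All 3 tested genes of the intestine list rose, with a median of 2.89 (camera adjusted p = 0.00156, adjusted p = 0.394 with an estimated correlation), and all 3 passed over the list alone. They were Lgals4, a gut galectin, at 2.89 ± 0.37, Vil1, the microvillus protein villin, at 2.34 ± 0.32, and Fabp1, which was high in KPC-OG 2 and KPC-OG 3 alone, as the liver genes were. With TPM the intestine list's camera adjusted p was 0.118 with a pseudocount of 1 and 0.0894 with 0.1. In the acute phase and acinar injury list 10 of 18 rose and 3 fell (10 and 4 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.00423, adjusted p = 0.458 with an estimated correlation). Lcn2, lipocalin 2, rose by 2.82 ± 0.28 and the calcium-binding protein gene S100a6 by 2.64 ± 0.23, while the members that fell, Reg1, Reg3a and Reg3d (-1.10, -1.45 and -1.56), encode secreted acinar proteins. The acute phase list's call was lost with library sizes only (adjusted p = 0.077), limma-voom (0.068) and TPM (0.731 and 0.873). Of 16 MAPK output genes 9 rose and none fell (10 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 2.18e-04, adjusted p = 0.458 with an estimated correlation). The EGF receptor ligand gene Areg rose by 2.55 ± 0.39, the receptor gene Epha2 by 1.58 ± 0.22 and the phosphatase gene Dusp6 by 1.22 ± 0.21. With TPM the MAPK list's adjusted p was 0.0599 and 0.0537.

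**Figure D2:**
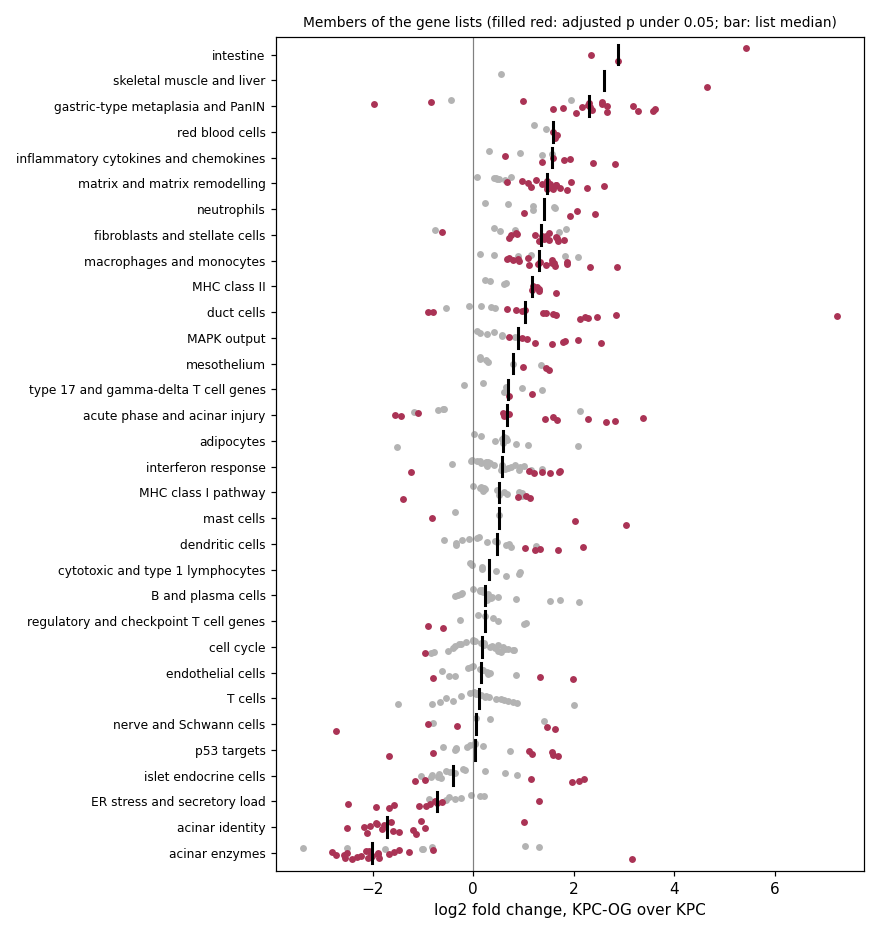
Log2 fold change of each tested member of the 32 gene lists, KPC-OG over KPC after TMM scaling. Onecut2 is placed at its lower bound. Red points passed an adjusted p of 0.05 over all genes, grey points did not, and the black bar is the list's median. The acinar enzyme list has the lowest median, -2.01, and the gastric-type list has a median of 2.31.

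Stromal genes rose as well. In the fibroblast and stellate cell list 15 of 22 rose and 1, Fap (-0.63), fell (19 and 2 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 3.45e-05, adjusted p = 0.487 with an estimated correlation). Col1a2, a chain of type I collagen, rose by 1.80 ± 0.34 from 208 ± 28.7 to 726 ± 333 CPM (SD, n = 4; edgeR adjusted p = 0.00325). Dcn, decorin, rose by 1.52 ± 0.28, Dpt, dermatopontin, by 1.32 ± 0.20, and Pdpn, podoplanin, by 1.69 ± 0.30. With TPM the fibroblast list's adjusted p was 0.0773 and 0.135. In the matrix and matrix remodelling list 21 of 28 rose and none fell (24 adjusted over the list alone), with a median of 1.46 (camera adjusted p = 6.88e-09, adjusted p = 0.458 with an estimated correlation). The proteoglycan genes Bgn and Vcan rose by 1.86 ± 0.29 and 1.46 ± 0.25, and the metalloproteinase genes Mmp14 and Mmp11 by 1.58 ± 0.26 and 2.27 ± 0.40. Of 9 mesothelium genes, Rspo1, Wt1 and Msln rose by 1.52, 1.45 and 0.99 and none fell (4 higher over the list alone, camera adjusted p = 0.185, adjusted p = 0.764 with an estimated correlation), and the Msln call was lost without any library other than KPC 3 (adjusted p up to 0.0812). With limma-voom calls were lost for Rspo1 (adjusted p = 0.0735) and Wt1 (0.0995), and with a transcript length offset for Wt1 (0.0792). Without KPC-OG 2 the mesothelium list had a camera adjusted p of 0.0461.

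Macrophage and inflammatory genes rose. In the macrophage and monocyte list 18 of 24 rose and none fell (21 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 5.84e-10, adjusted p = 0.403 with an estimated correlation). Arg1, arginase 1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, GRCm38), rose by 2.86 ± 0.24, from 1.94 ± 0.177 to 14.1 ± 3.74 CPM (SD, n = 4; edgeR adjusted p = 4.15e-04). Cd14, the lipopolysaccharide co-receptor, rose by 2.33 ± 0.22, and the complement genes C1qa and C1qb by 1.45 ± 0.18 and 1.62 ± 0.19. Of 11 inflammatory cytokine and chemokine genes 7 rose and none fell (9 over the list alone), with a median of 1.57 (camera adjusted p = 4.82e-04, adjusted p = 0.403 with an estimated correlation). The neutrophil chemokine Cxcl5 rose by 2.83 ± 0.32, the monocyte chemokines Ccl8 and Ccl2 by 2.39 ± 0.37 and 1.80 ± 0.42, and the alarmin Il33 by 1.37 ± 0.27. Of 10 neutrophil genes 4 rose and none fell (6 over the list alone), with a median of 1.40 (camera adjusted p = 0.0262, adjusted p = 0.487 with an estimated correlation). They were the cytokine gene Il1b at 1.93 ± 0.46, Hdc, histidine decarboxylase, at 2.43 ± 0.72, the G-CSF receptor gene Csf3r at 1.02 ± 0.32, and Padi4 at 2.06 ± 0.68. The calls were lost for Hdc without any library other than KPC 2 or KPC-OG 3 (adjusted p up to 0.0666), for Csf3r without KPC 1, KPC 4, KPC-OG 1, KPC-OG 3 or KPC-OG 4 (up to 0.0808), and for Padi4 without KPC 1, KPC 3, KPC 4, KPC-OG 3 or KPC-OG 4 (up to 0.109). The list's camera call was lost without KPC-OG 3 (adjusted p = 0.161), after thinning to one effective depth (adjusted p = 0.158), with a transcript length offset (0.0509), with library sizes only (0.666) and with TPM (0.535 and 0.422). It was also lost without both KPC-OG 2 and KPC-OG 3 (camera adjusted p = 0.0762). In the MHC class II list 6 of 10 rose and none fell (6 over the list alone), with a median of 1.18 (camera adjusted p = 0.00466, adjusted p = 0.584 with an estimated correlation). The peptide-loading gene H2-DMb1 rose by 1.64 ± 0.27 and the class II chain gene H2-Eb1 by 1.32 ± 0.34. The class II list's call was lost with library sizes only (adjusted p = 0.289), with TPM (0.255 and 0.448) and without both KPC-OG 2 and KPC-OG 3 (0.121). The list's mean log2 CPM was 2.48 and 2.65 in KPC 1 and KPC 3, where the B cell list was at -0.84 and -0.44. It was 4.18 and 4.63 in KPC 2 and KPC 4, where the B cell list was at 2.78 and 3.18, and 3.95 in KPC-OG 1, where that list was at -0.36. Among 19 dendritic cell genes Naaa, Ccl17, Itgax, Clec10a and Cd209a rose, by 1.24, 1.69, 1.34, 1.03 and 2.18, and none fell (4 over the list alone, camera adjusted p = 0.0762, adjusted p = 0.764 with an estimated correlation). Of these, Clec10a was lost without KPC 1, KPC 2 or KPC 4 (adjusted p up to 0.0746) and Cd209a without any library other than KPC 4 or KPC-OG 3 (adjusted p up to 0.105). Calls were also lost with limma-voom for Il1b (adjusted p = 0.141), Ccl2 (0.0682), Csf3r (0.132), Padi4 (0.196) and Clec10a (0.136), and with a transcript length offset for Il33 (0.0633), Csf3r (0.27), Padi4 (0.141), Clec10a (0.147) and Cd209a (0.0526). The dendritic list's camera adjusted p was 0.0305 without KPC 2, 0.0113 without KPC 4 and 0.031 without KPC-OG 1.

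None of 22 tested T cell genes, 8 cytotoxic and type 1 lymphocyte genes or 18 B and plasma cell genes passed the test, over all genes or over the list alone. Their medians were 0.12, 0.32 and 0.24 (camera adjusted p = 0.78, 0.739 and 0.719, and 0.954 for each with an estimated correlation). With library sizes only, camera placed the T cell and B cell lists below other genes (adjusted p = 2.03e-07 and 2.42e-07), and the cytotoxic list too (adjusted p = 0.0134). Camera was run there without re-centring on the median gene, where nearly all genes lay higher in KPC-OG. Re-centred, the medians were 0.11 for T cells, 0.32 for the cytotoxic list and 0.19 for B cells, close to those with TMM. The camera result thus depended on the scaling. Re-centring takes out the shift of all genes between the scalings, so these medians could not show whether the scaling mattered. Cd4 was at 4.94 ± 5.59 CPM in KPC and 5.74 ± 4.62 CPM in KPC-OG (SD, n = 4). Ccl5 was at 1.20 ± 1.29 and 2.39 ± 2.17 CPM, and Il2rb at 3.02 ± 3.19 and 3.0 ± 2.42 CPM. Ighm and Igkc, the immunoglobulin mu and kappa constant genes, had 30.1 ± 31.3 and 14.6 ± 14.6 CPM in KPC against 39.5 ± 31.8 and 64.8 ± 72.2 CPM in KPC-OG. With the B cell list's level as a covariate Igkc was called higher in KPC-OG (log2 fold change 1.45, edgeR adjusted p = 0.0244). Igkc is itself a member of that list. The spread lay within the groups, since the mean log2 CPM of the T cell list was -1.24 and -1.61 in KPC 1 and KPC 3 and -0.43 in KPC-OG 1, against 0.63 to 2.23 in the other 5 libraries. In the list of regulatory and checkpoint T cell genes 2 of 9 fell and none rose (2 over the list alone, median 0.24, camera adjusted p = 0.78, adjusted p = 0.954 with an estimated correlation). These were Ikzf2, which encodes Helios, at -0.61 ± 0.11, and Entpd1, which encodes CD39, at -0.90 ± 0.21. Within KPC neither gene followed the T cell list. Ikzf2 was at 18.14 and 16.98 CPM in KPC 1 and KPC 3, and at 17.84 and 17.22 CPM in KPC 2 and KPC 4. Entpd1 was at 97.59 and 50.15 CPM in KPC 1 and KPC 3, and at 57.47 and 62.48 CPM in KPC 2 and KPC 4. Their decreases therefore do not show a change in T cells. Which cells these transcripts came from was not tested. In the type 17 and gamma-delta T cell list 2 of 8 rose (2 over the list alone, median 0.69, camera adjusted p = 0.204, adjusted p = 0.487 with an estimated correlation, but fry adjusted p = 0.0147), the transcription factor gene Maf by 0.72 ± 0.20 and the cytokine receptor gene Il17re by 1.16 ± 0.37. The Maf call was lost without KPC 1, KPC 4 or KPC-OG 4 (adjusted p up to 0.0574) and the Il17re call without any library other than KPC 2 or KPC-OG 3 (adjusted p up to 0.0933). In the interferon response list 6 of 34 rose, 1 fell and 27 did not pass (3 and 1 over the list alone), with a median of 0.57 (camera adjusted p = 0.0242, adjusted p = 0.764 with an estimated correlation). The camera call was lost without KPC 1 (adjusted p = 0.0636), KPC 3 (0.135) or KPC-OG 2 (0.104), with a transcript length offset (0.0544), with library sizes only (0.901), with TPM (0.731 and 0.862), with fry (0.142) and without both KPC-OG 2 and KPC-OG 3 (0.205). Its mean log2 CPM was 1.54 and 1.35 in KPC 1 and KPC 3 and 2.60 and 2.51 in KPC 2 and KPC 4, and in KPC-OG it was lowest in KPC-OG 1 (2.43), as for the T cell and B cell lists. The antiviral genes Oasl2 and Oasl1 rose by 1.53 ± 0.26 and 1.71 ± 0.33 and the GTPase gene Gbp2 by 1.21 ± 0.22, while Mx1 fell by 1.24 ± 0.24. Of 17 MHC class I pathway genes Psme1, Psme2 and B2m rose by 1.14, 0.90 and 1.05, and the immunoproteasome gene Psmb10 fell by 1.40 (2 and 1 over the list alone, camera adjusted p = 0.106, adjusted p = 0.764 with an estimated correlation). Within groups the level of Psmb10 followed that of the acinar lists (r = 0.918). Psme1, Psme2 and B2m did not (r = -0.41, -0.04 and -0.369). Whether reads assigned to Psmb10 came from that gene was not tested. The class I list's camera adjusted p was 0.0452 without KPC 2, 0.0194 without KPC 4 and 0.0387 after thinning to one effective depth. The B2m call was lost without any library other than KPC 4 or KPC-OG 3 (adjusted p up to 0.125), and the Psme2 call without KPC 1, KPC-OG 1 or KPC-OG 2 (adjusted p up to 0.0769). Limma-voom gave adjusted p = 0.199 for Il17re and 0.077 for B2m, and a transcript length offset gave 0.0565 for B2m.

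**Figure D3:**
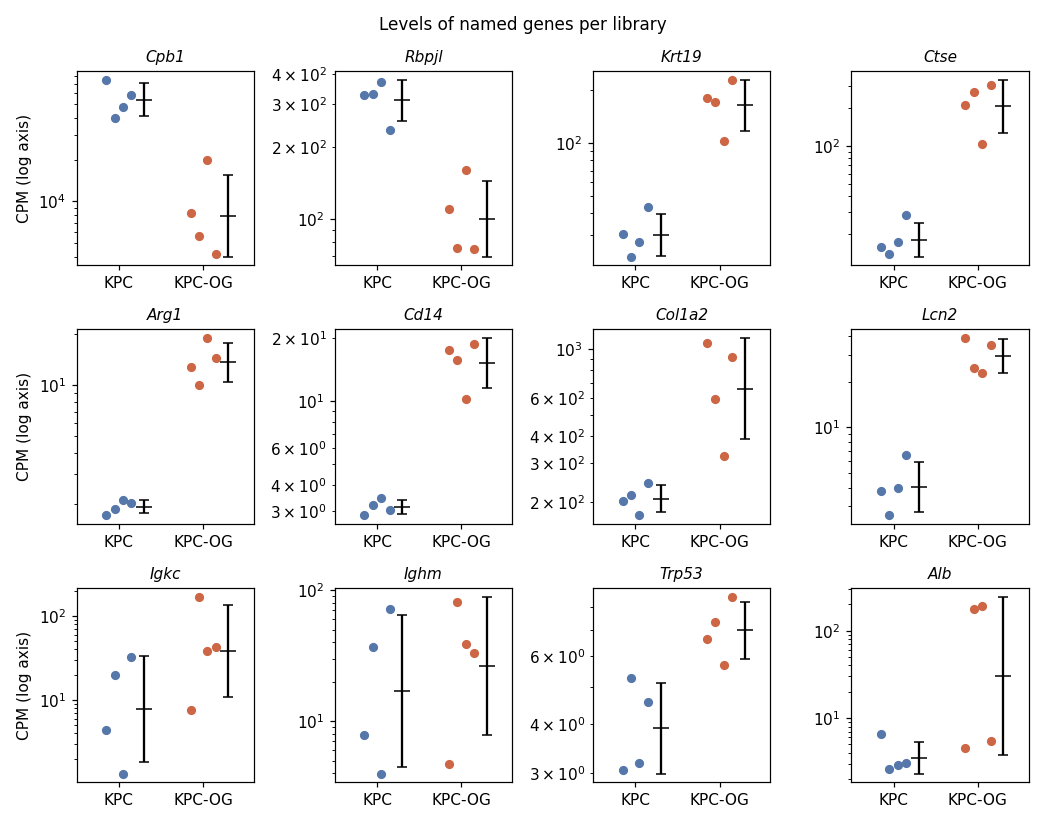
TMM-scaled CPM of 12 named genes in each of the 8 libraries, on a log axis. Each point is a library, and the dash and bar give the mean and SD of log2 values (n = 4). Krt19, Ctse, Arg1, Cd14, Col1a2 and Lcn2 lie higher in all 4 KPC-OG libraries, Igkc and Ighm spread within both groups, and Alb is high in KPC-OG 2 and KPC-OG 3.

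Other cell types the dissected organ can hold were checked by their own lists. Of 20 islet endocrine genes 4 rose and 2 fell (4 and 2 over the list alone), with a median of -0.41 and a mean of 0.03 (camera adjusted p = 0.739, adjusted p = 0.954 with an estimated correlation). The hormone genes Ppy and Pyy rose by 1.96 ± 0.37 and 2.10 ± 0.47, Chgb and Isl1 by 2.20 and 1.15, and Pcsk1, a prohormone convertase, was among those that fell (-0.96 ± 0.25). Of 16 endothelial genes Cldn5 and Vwf rose by 1.98 and 1.33 and the VEGF receptor gene Flt1 fell by 0.80 (2 and 1 over the list alone, median 0.16, camera adjusted p = 0.78, adjusted p = 0.954 with an estimated correlation), and the Vwf call was lost without KPC 1, KPC 4 or KPC-OG 4 (adjusted p up to 0.0647). Of 9 nerve and Schwann cell genes Ncam1 and S100b rose by 1.63 and 1.47, and 3 fell, among them the myelin gene Mbp by 0.33 and the chaperone gene Cryab by 0.91 (2 and 4 over the list alone, median 0.06 with a downward camera direction, adjusted p = 0.497, adjusted p = 0.64 with an estimated correlation, fry adjusted p = 0.0396). The calls were lost for S100b without KPC 1, KPC 2, KPC-OG 1, KPC-OG 2 or KPC-OG 4 (adjusted p up to 0.0587), for Mbp without KPC 1, KPC-OG 1, KPC-OG 2 or KPC-OG 4 (up to 0.0767), and for Cryab without any library other than KPC 2 or KPC-OG 4 (up to 0.144). None of 12 adipocyte genes passed (median 0.60 with a downward camera direction, adjusted p = 0.78, adjusted p = 0.954 with an estimated correlation), but KPC-OG 3 held 169 CPM of Cfd and 116 CPM of Fabp4, above the other 3 libraries of its group. Without KPC-OG 3 the adipocyte list had a median of -1.23 and a camera adjusted p of 0.0411, and without both KPC-OG 2 and KPC-OG 3 these were -1.05 and 0.0409. Camera also placed the adipocyte list below other genes with library sizes only (adjusted p = 4.33e-06) and with TPM (9.6e-05 and 1.82e-05). It was run there on values that were not re-centred. The list's re-centred medians were 0.08 with library sizes only and -0.03 and -0.12 with TPM. Of 5 mast cell genes the proteases Mcpt2 and Mcpt1 rose by 3.05 and 2.03 and Kit fell by 0.82 (2 and 1 over the list alone, camera adjusted p = 0.404, adjusted p = 0.584 with an estimated correlation, fry adjusted p = 0.023). Of 5 red blood cell genes Hbb-bs, Hbb-bt and Hba-a2 rose by 1.64, 1.66 and 1.58 (5 higher over the list alone, camera adjusted p = 0.0608, adjusted p = 0.584 with an estimated correlation), and calls were lost for Hbb-bs without KPC-OG 3 or KPC-OG 4 (adjusted p up to 0.0679), for Hbb-bt without any library other than KPC 2 or KPC-OG 1 (up to 0.0898), and for Hba-a2 without any library other than KPC-OG 1 (up to 0.0964). The red blood cell list's camera adjusted p was 0.0361 without KPC 2, 0.00197 without KPC-OG 1 and 0.0368 without KPC-OG 2. It was 0.046 with limma-voom and 0.0324 with sex as a covariate. The beta-globin genes Hbb-bs and Hbb-bt are near-identical copies of each other. The alpha-globin gene Hba-a2 has a near-identical copy of its own. The split of reads within each kind is uncertain. Of the liver and skeletal muscle list only Alb and Ttr could be tested. Alb, albumin, rose by 4.65 ± 1.43 (edgeR adjusted p = 0.0384), with 177 and 194 CPM in KPC-OG 2 and KPC-OG 3 and between 2.63 and 6.49 CPM in the other 6 libraries, and without those 2 libraries its log2 fold change was 0.43 (adjusted p = 0.436). The Alb call was also lost without any KPC library, KPC-OG 2 or KPC-OG 3 (adjusted p up to 0.0983). Fabp1 and Ahsg were also high in these 2 libraries. Ttr was at 16.6 ± 6.47 and 24.2 ± 13.1 CPM (SD, n = 4). Among the genes of this paragraph, limma-voom did not call Mcpt1 (adjusted p = 0.162), Vwf (0.227), Ncam1 (0.0604), S100b (0.117), Cryab (0.0582), Hba-a2 (0.0547) or Alb (0.459), and a transcript length offset ended the call of Vwf (0.0579).

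In the cell cycle list 1 of 26 genes fell and none rose (1 over the list alone), with a median of 0.18 (camera adjusted p = 0.809, adjusted p = 0.954 with an estimated correlation). The gene that fell was E2f1, a transcription factor of S phase entry, at -0.96 ± 0.21, and the proliferation marker Mki67 was at 46.8 ± 25.6 CPM in KPC and 27.4 ± 4.23 CPM in KPC-OG (SD, n = 4). Without KPC 3 the log2 fold change of Mki67 was -0.97 (edgeR adjusted p = 0.0366), and with the replicate number as a block it was -0.66 (edgeR adjusted p = 0.0435). Of 17 p53 target genes 5 rose and 2 fell (6 and 2 over the list alone), with a median of 0.03 (camera adjusted p = 0.78, adjusted p = 0.954 with an estimated correlation). The apoptosis genes Bax and Pmaip1 rose by 1.18 ± 0.20 and 1.58 ± 0.26 and Phlda3 by 1.68 ± 0.24, and Cdkn1a and Eda2r by 1.10 and 1.57, while the kinase gene Plk2 fell by 1.67 ± 0.22 and Zmat3 by 0.80.

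The floxed gene and the gene whose locus drives Cre were measured in every library. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, GRCm38) was detected in all 8 libraries and was higher in KPC-OG, at 4.01 ± 1.07 against 7.05 ± 1.19 CPM (SD, n = 4; log2 fold change 0.80 ± 0.23, edgeR adjusted p = 0.0215). That call was lost without KPC 1, KPC 3, KPC-OG 2 or KPC-OG 4 (adjusted p = 0.0614, 0.0541, 0.0572 and 0.0696), with limma-voom (0.0538) and with library sizes only, re-centred on the median gene (0.182). Ptf1a (ENSMUSG00000026735, chromosome 2, 19445663 to 19447501, GRCm38) fell by 1.03 ± 0.30 (edgeR adjusted p = 0.0264), a call lost without KPC 1, KPC 4, KPC-OG 2 or KPC-OG 4 (adjusted p = 0.0754, 0.0743, 0.0614 and 0.0748) and after thinning to one effective depth (adjusted p = 0.0642). The R26 transcript and Xist were not analysed here. The Y-linked gene Ddx3y was at 30.1 to 47.5 CPM in KPC 3, KPC 4, KPC-OG 1 and KPC-OG 3 and at 0 to 1.15 CPM in the other 4 libraries, so that each genotype had 2 libraries at each level. Uty and Eif2s3y were near 0 in the same 4 libraries, whereas Kdm5d was at 8.98 to 19.9 CPM there and at 24.1 to 43.5 CPM in the others. Kdm5d, Uty and Eif2s3y did not pass the test between the genotypes (log2 fold changes -0.11, 0.07 and 0.14, edgeR adjusted p = 0.895, 0.978 and 0.957). With sex from Ddx3y as a covariate 4553 genes were called. Calls were lost there for Padi4 (edgeR adjusted p = 0.056), B2m (0.0654), Cryab (0.0575) and Alb (0.0501), and gained for the Amy2a copies.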

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

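The tests on reads shared with Lars2, acinar content, scaling and liver genes were chosen after the results were seen.

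Of 352 sets of 4 values tested, 18 held a library far from the other 3 of its group, where chance gives about 17.6. In KPC-OG 3 these were Gdf7 at 1.31 CPM, Dlx6 at 20.9, Wdr17 at 2.55, Whrn at 40.9, Clec10a at 14.5, Psmb10 at 47.2, Cfd at 169, Fabp4 at 116 and Msln at 20.2, each above the other 3, and Oasl1 at 3.99 and Vil1 at 18.3, each below them. In KPC 3 Kit stood at 23.6 CPM and Ncam1 at 3.45, above the others. In KPC 1 Fabp1 stood at 0.382 CPM and Alb at 6.49, above the others. In KPC 2 Dlgap1 stood above the others at 0.188 CPM and Whrn below them at 202, and in KPC 4 Olfm4 stood above them at 1.52. Among 518 tested transcripts without a gene in the annotation, 48 were higher in KPC-OG and 38 lower (edgeR), a signal in data left out of the comparison.

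Besides Lars2, 45 genes were called over 8-fold lower in KPC-OG, and within groups their TMM-scaled levels followed that of Lars2 from library to library (median r = 0.92, exact one-sided permutation p = 0.00347; median rho = 0.857, exact permutation p = 0.00694; r = 0.824 without KPC-OG 2 and KPC-OG 3). Acinar content alone is argued against, since the genes followed Lars2 more closely than the acinar lists (median difference in r 0.23, lower quartile 0.106). TMM scaling alone is argued against by r with library sizes only (0.78, exact one-sided permutation p = 0.0278), though the rank correlation did not pass (median rho = 0.738, exact permutation p = 0.0556). Reads of an abundant RNA shared between Lars2 and these genes may be involved, but this cannot be told apart from regulation. Of the genes, 22.2% held a 20-base sequence of Lars2 against 16.8% of length-matched genes (one-sided p = 0.195 in a permutation-type test with 10000 random draws of length-matched genes). Only sequences of Lars2 itself were searched. An RNA that shares different stretches with Lars2 and with these genes would be missed, so the result does not decide the question. The genotype itself stays open as an untested biological explanation.

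Alb was at 177 and 194 CPM in KPC-OG 2 and KPC-OG 3, with Ahsg at 23.1 and 30.4 and Fga at 14.2 and 23.2. Liver tissue in these libraries is a candidate explanation, since 7 of 7 liver genes listed before the data were examined had their highest values in both, though Ttr is also expressed in pancreatic islets. No biological explanation was tested, and without both libraries Alb had a log2 fold change of 0.43 (edgeR adjusted p = 0.436).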

How the results depend on the processing

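Chosen after the data were seen were TMM without Lars2, unmatched transcripts, thinning, the length trend, leaving out both KPC-OG 2 and KPC-OG 3, the B cell covariate, 2 of the acinar share settings and re-centring of named genes.

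The count of changed genes stayed between 3446 and 5552 under RLE, TMM on fewer genes, DESeq2, limma-voom, both filters, a length offset, protein-coding genes, sex, replicate block (4895) and leaving out each library (3446 to 5428). With the block, calls were lost for Hdc, Padi4, Cryab, Hbb-bs, Hbb-bt, Hba-a2 and Alb and gained for Mki67, the Amy2a copies and the MHC class I list (camera adjusted p = 0.0357). The replicate numbers did not pair every library: deviations of like-numbered libraries correlated across genes, which are not independent, at 0.274 and 0.275 for numbers 1 and 2, the highest of the 16 pairs, but at 0.038 and 0.036 for numbers 3 and 4. Library sizes only gave 13177 genes (13078 higher, 99 lower), log2(TPM + 1) 12977 (12856 and 121) and log2(TPM + 0.1) 12937 (12817 and 120). The medians of all genes lay 1.74, 1.23 and 1.6 log2 units above that with TMM, so the counts and many directions moved with the scaling. Of the genes called with TMM, 1701, 1512 and 1518 were called in the opposite direction before re-centring. Among the named genes past the test, 20, 16 and 16 changed sign before re-centring. An adjusted p under 0.01 left 2490 (1168 and 1322) and glmTreat 1607 (917 and 690), by construction.

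Camera with an estimated correlation called 0 of 31 lists, against 15 with the preset and 17 with fry. Camera's direction turned with library sizes only for T cells (0.11), cytotoxic lymphocytes (0.32) and B cells (0.19), and with log2(TPM + 1) for T cells (-0.1) and B cells (0.07). It also turned with log2(TPM + 0.1) for T cells (0.22), B cells (0.39) and the acute phase list (0.71). The values in brackets are re-centred medians, whereas camera with library sizes only and with TPM was run on values not re-centred. A turned camera direction is therefore not a turned median. What turned camera's direction was not tested. With log2(TPM + 1), re-centring by the median shift of 1.23 put Rgs7bp (-0.21), Adcy8 (-0.12), Dlgap1 (-0.01) and Hdc (-0.11) below 0 by construction, since each was above 0 before it.

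Trp53 lost its call with limma-voom (0.79) and at 0.8 with the stricter p and glmTreat. Re-centred on the median gene, it also lost its call with library sizes only (0.83), log2(TPM + 1) (0.61) and log2(TPM + 0.1) (0.65). Without single libraries it ranged from 0.68 to 0.95. Ptf1a lost its call with re-centred log2(TPM + 1) (-0.7), thinning (-1.05), and at -1.03 with the stricter p and glmTreat, and ranged from -1.23 to -0.87 without single libraries. Of 126 named genes past the test, 22 lost their call without some library and 0 changed direction. The difference in acinar enzyme share passed the permutation test as a share of TPM (-16.15) and without Lars2 in the total (-18.17), but not with further amylase copies (-11.57) or without mitochondrially encoded genes (-8.85). For the separation of libraries, the first component held 51.7% with all genes and 41.8% to 54.5% without single libraries, and the genotypes separated each time. The intestine list was not the only list with too few genes to test after thinning, and the filter of 1 CPM in 4 libraries and 50 counts left 30 lists to test. The smaller depth of KPC limits calls of low genes.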

Other observations

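The tests of all cell types moving alike (the duct list included), depth and transcript length were chosen after the results were seen, and the counts of other splits of the libraries were planned.

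Acinar lists were lower while macrophage, fibroblast, matrix, duct and gastric-type lists were higher. A lower acinar share that raised all other cell types alike is argued against, since the macrophage list's median lay 1.15 log2 units above that of the endothelial list (permutation p = 5.1e-04, over genes, which are not independent). For the duct list a lower acinar share cannot be told apart from a change of its own, since its median lay 0.87 above that of the endothelial list (permutation adjusted p = 0.0797). A transcript length trend is argued against as the whole cause, since each list kept at least 96.1% of its median log2 fold change after the trend was removed. After thinning to one effective depth each list kept at least 97.2%. Thinning leaves the expected fold changes as they were, so it cannot decide whether depth played a part. A change in cell composition that goes with the genotype may remain, as a hypothesis found and tested on the same data.

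Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many changed genes (4859, highest other 4). This argues against chance for that count but does not exclude it, since 1 of 35 is the smallest share such splits can give. Every other split mixes the genotypes. Depth, the Lars2 share and the number of genes detected also differed between the groups, so the count does not tell the genotype apart from these. For the number of called lists chance cannot be excluded, since 18 of the 35 splits gave as many as the real one (15, highest other 21).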
